A study of Bdellovibrio bacteriovorus HD100 with 8 samples.

How the data were processed

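The series holds 8 one-colour microarrays of total RNA from attack-phase Bdellovibrio bacteriovorus HD100. Per the labels' protocols, the predator was grown on Escherichia coli MG1655 prey in 3 subcultures, passed through a filter and concentrated, and aliquots of each subculture were mixed with 0, 1 or 2 mM indole for 30 min. The labels number the samples as replicates 1 to 3 at 0 and 1 mM and 1 to 2 at 2 mM, and do not say that the number names the subculture. They call the samples independent. Cy3-labelled cRNA was made from 100 ng of RNA with a whole-transcriptome kit, per the labels' protocols. The submitters' processing notes name Agilent Feature Extraction 9.1, while the file headers give version 10.5.1.1 with the protocol GE1_105_Dec08.

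Each array's scanner file, as deposited, holds intensity values per spot: the processed signal, from which the software had already subtracted background, the median signal and local background, and flags for outliers, saturation and being well above background, per the file headers. The deposited matrix holds a linear ratio. Set against the scanner values, it was each spot's processed signal divided by that array's 75th percentile over all non-control spots, to within 1% for 100% of the values of 1 or more, and it was neither logged nor centred per gene. Its column medians ran from 0.368 to 0.784, and 15 to 239 of its 12828 rows were blank per array. The scanner file of 0 mM replicate 2 keeps full precision, and the others hold values rounded to 3 digits. No column of the matrix belonged to another series.

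All 8 arrays lay on 1 slide and were read in 1 scan, so neither separates the groups. Row 1 of the slide held the 0 mM arrays and 1 mM replicate 1, and row 2 held the other 4. No reference genome or annotation was used. Probe identifiers give each ORF's start, end and strand on the chromosome sequence the array was designed on (1672 ORFs on the plus and 1535 on the minus strand, between positions 2755 and 3782628), and 100% of the lengths are multiples of 3, so they are coding lengths. Each ORF had 1 probe in 4 spots. None of the 29 gene lists fixed before the data were examined could be filled from these identifiers, so no gene list was tested, and runs of neighbouring ORFs, a choice made after seeing the data, took their place. For the same reason the rule for named genes reduced to its last part: the 2 largest changes in each direction against 0 mM, and the largest in each direction between the doses, among ORFs with an adjusted p under 0.05 and every array of the one group beyond every array of the other. Since values at the background have no order, only ORFs above background on every array of both groups, with no missing value in them, were ranked, a restriction made after a first listing held ORFs with 1 usable array in a group. The parts of the rule that need a product or a gene name, 8 more genes in each direction against 0 mM and a set of genes always reported, could not be applied.

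Spots marked as non-uniform or population outliers were left out (259 to 695 non-control spots per array), saturated spots would have been kept, and none was marked as saturated. A probe counted as well above background on an array when at least 0.5 of its unmarked spots were. Since under 20% of the spots of an array were well above background, log2 processed signals were scaled by subtracting each array's 75th percentile over the spots of the 188 non-control probes above background on all 8 arrays, 183 of them ORFs. This replaced the 75th percentile over all non-control spots that had been planned, was chosen after the signal levels and before any test. The form first planned as the main scaling was then run as an alternative, a use added after seeing the data. Spots of a probe were averaged. ORFs above background on at least 2 arrays were kept, 763 in all, and 73 of them had an array on which every spot was marked as an outlier. For 2 ORFs no comparison with 0 mM could be fitted. The spike-in level is the mean log2 signal of the 5 E1A probes, Agilent's one-colour spike-in controls, that were above background on every array, and the Bd_r level that of 3 probes. Spots marked as outliers were kept for both kinds, because 88.5% of the spots of the Bd_r probes and 53% of those of the 5 spike-in probes, over all arrays, carried that mark. The amount of spike-in added is not given in the sources used here.

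The tests of ORFs were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend) on all 8 arrays in 3 groups, with Benjamini-Hochberg adjustment and a threshold of 0.05. An ORF that no array of a group showed above background has only a limit there. Its fold was given as "at least", from the mean of the brighter group against the mean, per array, of the higher of its own value and the lowest value of any ORF above background. Runs were tested with camera, preset correlation 0.01, on ORFs without missing values (690 of the 763), with an estimated correlation and fry beside it. Dose order was tested with an exact permutation test on the sum of signs over pairs of arrays at different doses. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the plots.

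The fit was tested on simulated data with 763 genes per comparison, 200 of them changed. At a change of 2 in log2, 100% of the 100 changed genes were recovered in each comparison. At a change of 1, 67% were recovered for 1 mM against 0 mM and 66% for the other 2 comparisons, with 5, 13 and 26 false calls. In simulated runs, 1 moved run was called and 0 of the others. The simulated ORFs varied independently of each other, while neighbouring ORFs in the data changed together. The simulation therefore does not show how often camera calls unmoved runs in these data.

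Alternatives planned before the data were examined were other normalizations, normexp background correction (on the median signal, since the files hold no mean signal, with an offset of 50), other filters on dim ORFs, the matrix values, a fit of only the groups compared, a replicate block, other variance models, leaving out each array, and a threshold on the fitted fold. Those added after seeing the data were scaling to the spike-ins or to the Bd_r probes, keeping outlier spots, the slide row, leaving out both arrays of raised background, and all settings for runs and for the ORF level. The probe of highest signal was not run as an alternative because each ORF has 1 probe, nor the slide as a block because there is 1 slide.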

Results

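Transcript levels were measured in attack-phase cells of the predatory bacterium Bdellovibrio bacteriovorus HD100, the free-swimming stage that seeks bacterial prey, after 30 min in HEPES buffer with 0, 1 or 2 mM indole. Indole is a signal molecule that many bacteria make from tryptophan. The series title places the question in the effect of indole on predation and on release from the bdelloplast, the rounded prey cell in which the predator grows. Total RNA of 3 samples at 0 mM, 3 at 1 mM and 2 at 2 mM was labelled with Cy3 and hybridised to 8 one-colour arrays on 1 slide. The array carried probes for 3207 open reading frames (ORFs), each probe printed in 4 spots. The files name an ORF only by its start, end and strand on the HD100 chromosome and do not pair these positions with gene names, so ORFs are given here by position, as the probe identifiers give it.

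The arrays were dim. Between 7.98% and 19.8% of the 15208 non-control spots of an array were well above background, and 2356 of the 3207 ORFs were well above background on none of the 8 arrays. The 763 ORFs that were well above background on at least 2 arrays were tested. None of the 77 negative control spots was well above background on any array, but their median signal was 1.78 on 1 mM replicate 1 and 2.05 on 2 mM replicate 2 against 1 to 1.19 on the other arrays. Over the 183 ORFs above background on all 8 arrays, the correlation between arrays across ORFs was 0.969 to 0.982 within the 0 mM group, 0.934 to 0.963 within the 1 mM group and 0.926 for the 2 mM pair. It was 0.776 to 0.874 between 0 and 1 mM arrays and 0.396 to 0.509 between 0 and 2 mM arrays. ORFs are not independent replicates, and the small number of arrays limits the precision of every value below.

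The first comparison asked how much ORF signal the arrays held at each dose. The number of ORFs well above background was 701 ± 28.7 at 0 mM (SD, n = 3), 482 ± 109 at 1 mM (SD, n = 3) and 307 ± 24.0 at 2 mM (SD, n = 2). The median ORF signal, set against the 5 spike-in control probes that were above background on every array, was -3.93 ± 0.28 in log2 at 0 mM (SD, n = 3), -5.02 ± 0.22 at 1 mM (SD, n = 3) and -5.92 ± 0.15 at 2 mM (SD, n = 2). This was 2.13-fold lower at 1 mM and 3.95-fold lower at 2 mM than at 0 mM. The 3 probes whose identifiers have the form of Bdellovibrio rRNA locus tags (Bd_r) took 45.4% to 48.4% of the non-control signal at 0 mM, 56.2% to 60.9% at 1 mM, and 67.7% and 56.8% on the 2 mM arrays. Their level against the spike-ins was 5.72 ± 0.17 in log2 at 0 mM, 5.75 ± 0.15 at 1 mM and 5.80 ± 0.30 at 2 mM (SD, n = 3, 3 and 2). None of their spots was marked as saturated. Against the Bd_r probes, the median ORF signal was 4.17-fold lower at 2 mM than at 0 mM.

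All 8 arrays followed the order of the doses for the number of ORFs above background and for the ORF signal against spike-ins or Bd_r probes. In a two-sided exact permutation test of the dose order over 560 arrangements of the arrays, p was 0.00357 for each of these 3 measures, the smallest value the design can give, and 0.00714 after Benjamini-Hochberg adjustment over 6 measures. The adjusted exact p was 0.96 for the Bd_r level against spike-ins and 1 for the spike-in level itself. Between pairs of groups, the exact permutation p could not go below 0.1. The falls of 2.13-fold and 3.95-fold come from medians over the 690 tested ORFs without missing values, many of which were near background at 2 mM. Over the 183 ORFs above background on all arrays the change at 2 mM was -1.17 in log2. Being above background on both 2 mM arrays favours ORFs with small falls. The 690 had to be above background on at least 2 arrays, which more ORFs were at 0 mM than at 2 mM. That filter favours falls. The level of these 183 per spike-in was -2.58 to -2.25 at 0 mM, -2.90 to -2.67 at 1 mM, and -3.63 and -3.55 at 2 mM. Their fall at 1 mM was thus also smaller. Row 1 of the slide held the 0 mM arrays and 1 of the 1 mM arrays, and row 2 held the others. Within row 2 the ORF signal per spike-in differed by -0.94 between 2 and 1 mM, against -0.89 over both rows. Within row 1 the 1 mM array differed from the 0 mM mean by -1.18, against -1.09 over both rows. No row held both 0 and 2 mM arrays, and along each row the order of the slots followed the doses.

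**Figure D1:**
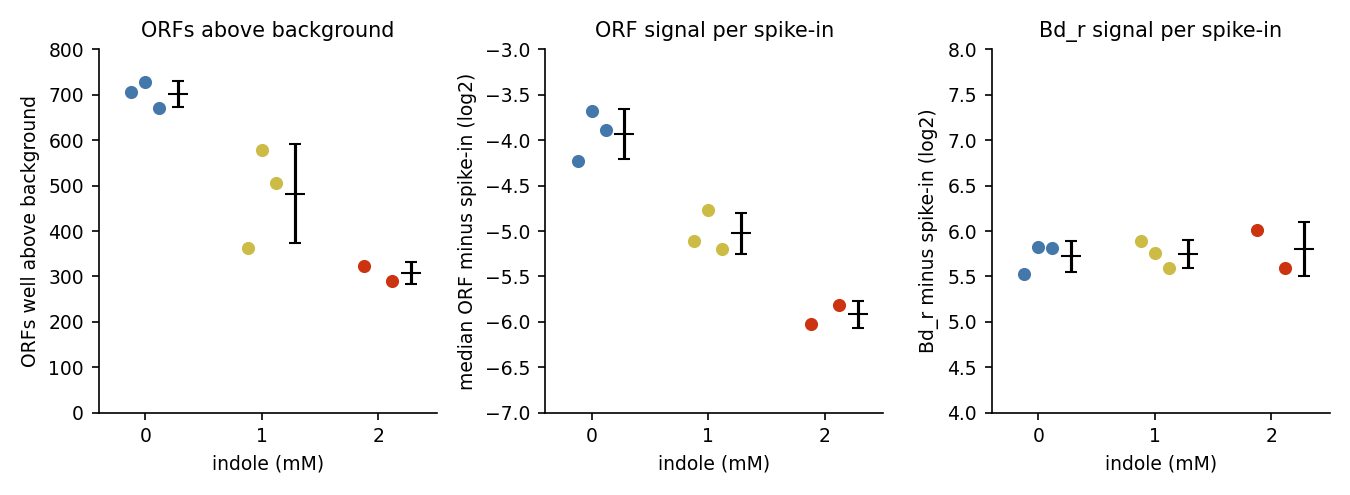
Values of each array at 0, 1 and 2 mM indole: the number of ORFs well above background, the median ORF signal minus the spike-in level in log2, and the Bd_r level minus the spike-in level in log2. Points are arrays, and black bars are the mean ± SD beside them. The first 2 measures fall from 701 to 307 ORFs and from -3.93 to -5.92, while the Bd_r level stays between 5.53 and 6.01.

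For the comparison of single ORFs, each array was scaled to the probes above background on all arrays, so the changes below are relative to those probes. At 1 mM against 0 mM, 334 of 761 ORFs changed, of which 65 rose and 269 fell. The median change was -0.27 in log2. With ORFs that were dark in a group, that is, well above background on none of its arrays, set at their limit, 26 of the changed ORFs rose and 149 fell by at least 2-fold. Among the 353 ORFs above background on every array with usable spots in both groups, 39 rose and 56 fell. A further 117 of the falls were to a signal not well above background on any 1 mM array.

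The largest rise measured on both sides at 1 mM was that of the ORF at 2316430–2317011 on the plus strand, with a coding length of 582 bases. Its scaled log2 signal was -2.47 ± 0.14 at 0 mM and -0.22 ± 0.33 at 1 mM (SD, n = 3 each), a 4.75-fold rise. The ORF at 1650146–1650667 on the minus strand rose from -1.57 ± 0.06 to -0.07 ± 0.35 (SD, n = 3 each), or 2.82-fold. The largest fall measured on both sides was that of the ORF at 572029–572439 on the plus strand, from 1.82 ± 0.28 to -0.96 ± 0.74 (SD, n = 3 each), a 6.88-fold fall. The ORF at 3241586–3241954 on the minus strand was 5.13-fold lower, with a log2 change of -2.36 ± 0.36 (SE). The limma adjusted p was 8e-06 for the first of these, 0.000166 for the second, 2.0e-05 for the third and 0.000154 for the fourth. The rise at 1650146 was 0.91 in log2 and no longer past the threshold when arrays were scaled to the median of all non-control spots (limma adjusted p = 0.0684). Over its 24 alternatives the log2 change ranged from 0.517 to 1.78 and the limma adjusted p from 1.53e-07 to 0.0684, past the threshold in the other 23. The sizes of the other changes also depended on the processing. Over the alternatives, the rise at 2316430 ranged from 0.60 with normexp to 2.44, the fall at 572029 from -3.46 to -1.51 with normexp, and the fall at 3241586 from -2.94 to -0.77 with normexp.

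The balance of rises and falls depended on the scaling and on the filter on dim ORFs. Scaled to the spike-ins, 18 ORFs rose and 414 fell at 1 mM, which put 4.17% of the calls on the side of the rises in place of 19.5%. The share was 3.02% with the Bd_r probes, 2.55% with the median of all non-control spots and 35.6% with quantile normalization. It was 62.7% (42 rises and 25 falls) among the 183 ORFs above background on all arrays, 54.8% (340 and 280) without a filter on dim ORFs and 24.6% (32 and 98) with normexp background correction. The 183 leave out every ORF that was dark in a group, and the main scaling was set mainly on them. Without the filter, most ORFs were above background on no array (2356 of 3207). The median change under spike-in scaling was -0.80, a shift of -0.52 against the main scaling. Of the 65 rises, 18 were also called as rises under spike-in scaling.

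At 2 mM against 0 mM, 482 of 761 ORFs changed, of which 115 rose and 367 fell. The median change was -0.62 in log2. With ORFs that were dark in a group set at their limit, 68 rose and 184 fell by at least 2-fold, and 4 rose and 10 fell by at least 8-fold. No fold was given to 3 changed ORFs that were dark in both groups. Among the 260 ORFs above background on every array with usable spots in both groups, 77 rose and 66 fell. For 278 of the falls no 2 mM array had a signal well above background. For 233 of them a lower limit above 1 could be given, with a median of at least 2.21-fold and a highest limit of at least 11.6-fold. For 11 of the rises no 0 mM array had a signal well above background, and these rose by at least 2.28-fold to at least 14.2-fold. A further 10 rises were of ORFs that no 2 mM array showed well above background.

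The largest rise measured on both sides at 2 mM was that of the ORF at 2061343–2061969 on the plus strand, with a coding length of 627 bases. Its scaled log2 signal was -0.40 ± 0.31 at 0 mM (SD, n = 3) and 3.29 ± 0.27 at 2 mM (SD, n = 2), a 12.9-fold rise. At 1 mM only 1 array had spots of this probe that were not marked as outliers, with 1.75. The ORF at 1650146–1650667, which also rose at 1 mM, was 6.77-fold higher at 2 mM, with 1.19 ± 0.07 (SD, n = 2) against -1.57 ± 0.06 (SD, n = 3). Under spike-in scaling these rises were 2.61 and 1.67 in log2. The largest fall measured on both sides was again that of the ORF at 572029–572439, which was 15.2-fold lower at 2 mM, with -2.11 ± 0.25 (SD, n = 2) against 1.82 ± 0.28 (SD, n = 3). The ORF at 1918731–1919708 on the plus strand, with a coding length of 978 bases, was 11.8-fold lower, with -2.84 ± 0.01 against 0.71 ± 0.33 (SD, n = 2 and 3). On 2 mM replicate 2, an array of raised background, its value of -2.85 was the lowest of any ORF above background. Its level at 2 mM was thus at the edge of what that array could measure. The limma adjusted p of each of these 4 changes rounded to 2e-06. Over the alternatives, the rise at 2061343 ranged from 2.24 to 4.00 in log2 and that at 1650146 from 1.03 with normexp to 3.12. The fall at 572029 ranged from -5.38 to -1.59 with normexp and that at 1918731 from -5.00 to -0.83 with normexp, so the size of these falls depends on the processing.

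Scaled to the spike-ins, 26 ORFs rose and 602 fell at 2 mM, so that 4.14% of the calls were rises in place of 23.9%. The share was 3.87% with the Bd_r probes, 1.62% with the median and 10.3% with the 75th percentile of all non-control spots, 10.4% with the deposited matrix values and 26.8% with quantile normalization. Rises outnumbered falls with normexp background correction (165 and 95, or 63.5%), without a filter on dim ORFs (2319 and 357, or 86.7%) and among the 183 ORFs above background on all arrays (61 and 51, or 54.5%). The set without a filter is mostly ORFs above background on no array (2356 of 3207), and its median change was 1.41 in log2. The 183 ORFs leave out each of the 278 falls to a signal not well above background at 2 mM. The median change was -1.73 with spike-in scaling, a shift of -1.08. The 26 rises under spike-in scaling were all among the 115. By signal level, with the tested ORFs parted by mean signal over all arrays into 4 groups of about equal size, the rises numbered 15, 24, 33 and 43 and the falls 94, 108, 102 and 63 from the dimmest to the brightest group. That mean includes the treated arrays. A rise thus moves an ORF toward the brighter groups and a fall toward the dimmer ones, so part of this order is built in. The strands did not stand apart, with 61 rises and 184 falls on the plus strand and 54 rises and 183 falls on the minus strand.

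**Figure D2:**
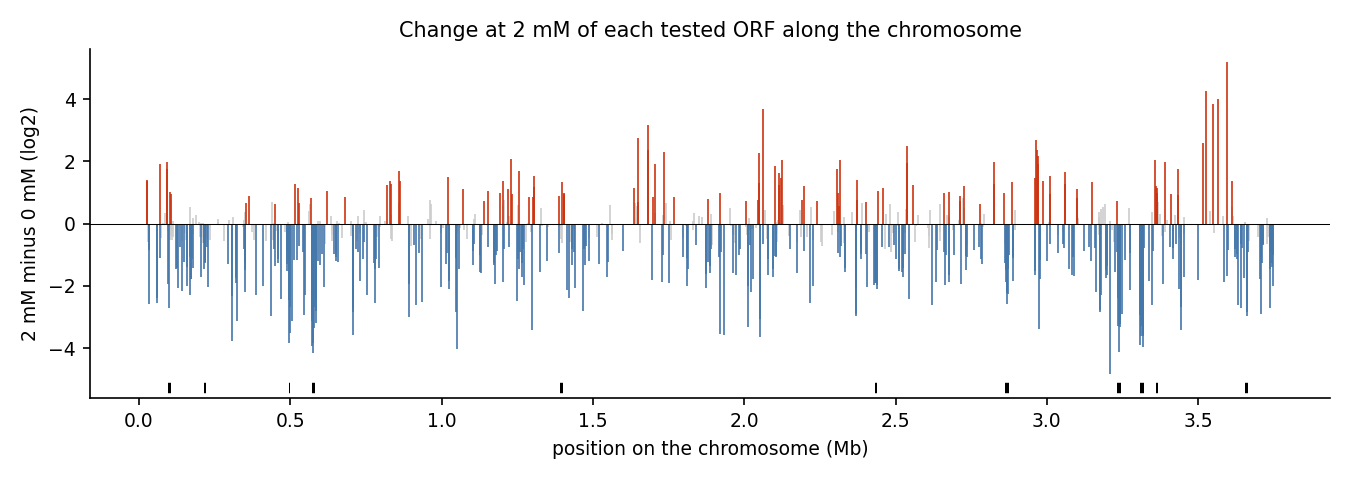
Change at 2 mM of each tested ORF by its position on the chromosome in Mb, as 2 mM minus 0 mM in log2 under the main scaling. Red lines are the 115 rises, blue lines the 367 falls and grey lines ORFs not past the threshold. Black marks at the bottom are the 12 runs of neighbouring ORFs tested together.

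The 2 doses were then set against each other. At 2 mM against 1 mM, 172 of 763 ORFs changed, of which 46 rose and 126 fell. With dark ORFs set at their limit, 23 rose and 60 fell by at least 2-fold, and 7 of the changed ORFs were dark at both doses and got no fold. For 84 of the falls no 2 mM array was well above background. The largest rise measured on both sides was that of the ORF at 1228736–1230649 on the plus strand, from 0.06 ± 0.23 at 1 mM (SD, n = 3) to 1.62 ± 0.00354 at 2 mM (SD, n = 2), a 2.94-fold rise. The largest fall measured on both sides was that of the ORF at 1918731–1919708, which was 4.28-fold lower at 2 mM than at 1 mM. As said above, its value on 2 mM replicate 2 was the lowest of any ORF above background on that array. The limma adjusted p was 0.00107 for the rise and 0.00105 for the fall. The rise at 1228736 was not past the threshold with the median of all non-control spots, where it was 0.69 (limma adjusted p = 0.228), and the fall at 1918731 was not with normexp background correction, where it was -0.18 (limma adjusted p = 0.182). Over their 25 alternatives the log2 changes ranged from 0.69 to 1.67 and from -2.96 to -0.18, and the limma adjusted p from 2.16e-08 to 0.228 and from 2.54e-10 to 0.182. Within slide row 2 alone, with 2 arrays of each dose, 152 ORFs changed. Without 2 mM replicate 1, 68 ORFs passed the threshold in place of 172. Under spike-in scaling, 6 ORFs rose and 342 fell, which put 1.72% of the calls on the side of the rises in place of 26.7%, and the median change was -0.75 in place of -0.17. With the Bd_r probes the share was 1.80%, with the median of all non-control spots 0.893%, with their 75th percentile 6.84%, with the matrix values 7.45% and with quantile normalization 18.8%. It was 92.1% (1821 rises and 156 falls) without a filter on dim ORFs, 45% (27 and 33) with normexp and 43.9% (29 and 37) among ORFs above background on all arrays. As above, the set without a filter is mostly ORFs above background on no array, and the last set leaves out ORFs dark at 2 mM.

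Of the 252 ORFs above background on every array with usable spots in all groups, 139 changed at 2 mM, and for 130 of these the change at 1 mM had the same sign and was smaller. They were chosen by their change at 2 mM, which favours that order. In the test of 2 mM against 1 mM, 118 of the ORFs that fell at 2 mM against 0 mM were called lower and 36 of those that rose were called higher. Falls shared by both doses numbered 236, where lists independent of each other would share 130, and shared rises numbered 54, where they would share 9.82. No ORF was called in opposite directions. Across 761 ORFs, which are not independent replicates, the changes at both doses had a Pearson correlation of 0.844 and a Spearman correlation of 0.857, and 85.8% had the same sign. Both comparisons use the same 3 control arrays. In 100 simulations of unchanged groups against shared controls the mean Pearson correlation was 0.449 and 65.0% of signs agreed. The observed covariance was 1.17 against a simulated mean of 0.036 and highest value of 0.0434. The controls were too few to be split, so part of the overlap may come from sharing them.

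Neighbouring ORFs were described together, a choice made after seeing the data because the files hold no gene names. There were 12 runs of same-strand ORFs with gaps of at most 100 bases and at least 5 tested members. At 1 mM the run at 3232783–3243684 on the minus strand held 12 tested ORFs, of which 11 fell and 1 did not pass the test. The run at 3307572–3321906 on the minus strand held 13, of which 12 fell. All 6 tested ORFs of the run at 573035–582975 and all 5 of the run at 494983–499332, both on the plus strand, fell. In the run at 3307572–3321906 the median fall at 1 mM was 3.82-fold, whether or not dark members were set at their limit. In the others, with members that were not above background set at their limit, it was at least 5.65-fold, 6.14-fold and 5.49-fold, in the order given. Under spike-in scaling 11, 13, 6 and 5 members of the 4 runs fell. The run at 2867861–2873687 on the minus strand, a run of short ORFs with a median coding length of 369 bases, had 10 of 12 members lower, and its neighbour at 2863139–2867534 had 5 of 5. Their median falls were at least 2.27-fold and 2.28-fold.

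The run at 3361205–3367327 on the plus strand went the other way at 1 mM. All 5 of its tested members rose, with a median of at least 2.22-fold, and 3 of them also rose under spike-in scaling. Of the other 5 runs, those at 213467–220889 and 2433433–2440310 each had 4 members that fell, the run at 3655803–3665900 had 3, and the runs at 96873–106344 and 1392270–1401331 had 1 changed member each.

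At 2 mM the same 4 runs also held falls, with 11 of 12, 12 of 13, 6 of 6 and 5 of 5 members lower, but 11, 9, 6 and 4 of their tested members had no 2 mM array well above background. Their median falls were then at least 3.72-fold, 5.44-fold, 3.96-fold and 5.45-fold. In the first of them 1 member rose. The run at 2433433–2440310 on the minus strand had no member that was dark on every 2 mM array, and all 6 of its members fell at 2 mM, by a median of 3.76-fold. Of these 6, 5 were also called lower at 2 mM than at 1 mM, and the median over all 6 was 2.17-fold lower. The run of short ORFs had 10 of 12 members lower, and none of the 12 was well above background on a 2 mM array. In the run that rose at 1 mM, 4 of 5 members rose at 2 mM under the main scaling, but under spike-in scaling none did and 1 fell, and 3 of the 5 had no 2 mM array well above background.

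As sets, camera with its preset correlation of 0.01 called 7 of the 12 runs at 1 mM, 6 lower and 1 higher, and 6 at 2 mM, 5 lower and 1 higher. When the 6 arrays at 0 and 1 mM were split into other groups of 3, the highest count of runs was 8, and 10 splits are too few for a share under 0.05. With an estimated correlation 0 runs were called, and the lowest adjusted p was 0.0724 at 1 mM and 0.278 at 2 mM. Against 1 mM, 0 runs were called at 2 mM (1 at an unadjusted p under 0.05), with the lowest camera adjusted p of 0.0528 for the run at 2433433–2440310. The fry test, which asks whether the members of a run move one way, called 10, 10 and 1 of the 12 runs. Under spike-in scaling, camera called 3 runs at 2 mM in place of 6. A further 36 runs held 3 or 4 tested members. In 9 of these every member fell at 2 mM, in 2 every member rose, and in 4 none passed the test.

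**Figure D3:**
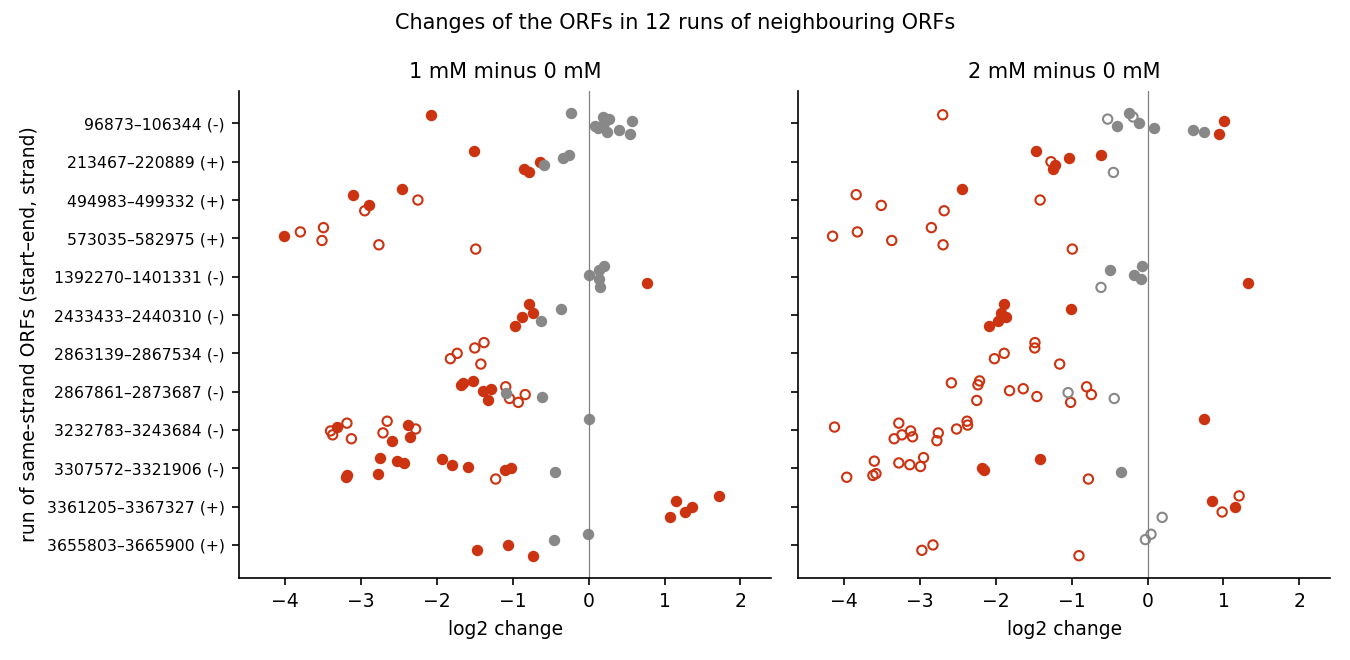
Log2 change of every tested ORF in the 12 runs of neighbouring ORFs, at 1 mM (left) and 2 mM (right) against 0 mM under the main scaling, each row being a run named by start, end and strand. Red points passed the threshold and grey points did not, and open points are ORFs with no treated array well above background, whose change is a fitted value. The run at 3361205 is the only row in which every point is red and above zero at 1 mM, and under spike-in scaling 3 of its 5 members rose.

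The array also held 2342 probes in single spots with identifiers of the form b followed by 4 digits, which is the form of locus tags of Escherichia coli K-12, the species grown as prey. The files do not state their organism. Between 0.685% and 1.63% of them were well above background on an array. The share was 0.842% ± 0.203 at 0 mM, 1.23% ± 0.407 at 1 mM and 0.920% ± 0.0908 at 2 mM (SD, n = 3, 3 and 2), with an adjusted exact permutation p of 0.664 for the dose order. Of the 25 that were above background on at least 2 arrays, limma called 0 in each comparison, under the main scaling and under spike-in scaling, and 0, 8 and 1 had an unadjusted p under 0.05 at 1 mM, at 2 mM and between the doses. Their median change at 2 mM against 0 mM was 1.06 in log2 under the main scaling and -0.07 under spike-in scaling.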

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

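The settings for spike-ins, Bd_r probes, all non-control spots at the 75th percentile, outlier spots, slide row and raised background, and all settings for runs and for the ORF level, were chosen after seeing the data. At 1 mM against 0 mM, 22 of 25 alternatives gave a count within 1.5 times the 334 ORFs, and at 2 mM against 0 mM 22 of 25 did for the 482. The exceptions were normexp (130 and 260 ORFs), no filter on dim ORFs (620 and 2676) and ORFs above background on all arrays (67 and 112, of 183 tested, so that fewer ORFs could be called). The cause was not tested for normexp. The alternatives were not all separate checks. For 1 mM against 0 mM, fitting only the groups compared and leaving out either 2 mM array gave the same ORF results. A lone 2 mM array has no spread of its own to add to the fit. At 2 mM against 1 mM the 172 ORFs became 260 with quantile normalization, 336 with the median and 263 with the 75th percentile of all non-control spots, 282 with the matrix values, 348 with spike-in and 334 with Bd_r scaling, 60 with normexp, 1977 without a filter and 66 with ORFs above background on all arrays. The cause was not tested. Leaving out each array in turn gave 253 to 348, 374 to 498 and 68 to 244 ORFs, the lowest of the last without 2 mM replicate 1. A lone remaining array is assumed to vary like the others. Of the ORFs called under the main setting, 0 were called in the opposite direction in these alternatives.

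The replicate block gave 353, 483 and 222 ORFs in the order of the comparisons. Same-numbered arrays had correlations of their deviations between 0.0369 and 0.376, all positive but not all over 0.1. Of the 8 arrays, 5 correlated best with their own number. These values do not settle whether the numbers pair samples, so the replicate block was kept as an alternative. Within slide row 2 alone, 152 ORFs changed between 1 and 2 mM, and with the slide row as a block 293, 359 and 249 did. Without both arrays of raised background the counts were 328, 495 and 228.

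Of the runs, 7 were called at 1 mM, which became 15 of 94 without a filter, 1 of 1 with ORFs above background on all arrays, and 0 with an estimated correlation. The 6 runs at 2 mM became 12 of 94, 1 of 1, 3 with spike-in and 3 with Bd_r scaling, 10 with fry and 0 with an estimated correlation. The 0 runs between the doses became 11 of 94 without a filter, and 1 with normexp, ORFs above background on all arrays, the matrix values, only the groups compared, trend and robust, spike-in scaling, outlier spots kept, slide row 2 alone or fry. Leaving out each array gave 7 to 9, 4 to 7 and 0 to 1 runs. The ORF level per spike-in fell by 1.86 to 2.13 in log2 with an array left out. Of 240 values for the 10 changes of named ORFs under alternatives, 237 stayed past the threshold, 3 did not and 0 turned. The 240 include the slide row block, which rests on 1 array against 0 mM, and a fit that is counted more than once. No value could be given for gene lists. Signal over background limits the sizes of falls: 278 of the 367 falls at 2 mM ended below it.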

Other observations

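The bins, the explanations and their tests, and the tests of neighbours and of other splits were chosen after the results were seen, as was the ORF level per spike-in. The rises that held under spike-in scaling were looked at by place. The 26 ORFs that rose at 2 mM under that scaling were counted in bins of 100 kb. The bin from 3500001 to 3600000 held 5 of them among 13 tested ORFs, and its 5 rises under the main scaling were all rises under spike-in scaling. The bin from 2900001 to 3000000 held 4 among 12, and that from 1600001 to 1700000 held 3 among 12. With Fisher's exact test over 38 bins and both directions (76 tests), no bin held more or fewer of the main scaling's rises or falls than the rest after adjustment. The lowest adjusted p was 0.0912, and 12 of the 76 had an unadjusted p under 0.05. The counts per bin of the 26 rises under spike-in scaling were not tested, so these results do not bear on them.

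The ORF signal per spike-in fell by 1.98 in log2 from 0 to 2 mM. The tables argue against a lower sensitivity of the 2 mM arrays, since the spike-in level differed by 0.072 ± 0.297 (SE). The median per array over the 25 b-number probes tested, per spike-in, differed by 0.106 ± 0.103 (SE) between the groups. The median of their changes probe by probe was -0.0737. This argues against a rise of the RNA that these probes measure. They are 25 of 2342 and their organism is not stated, so displacement by other prey RNA stays open. The tables argue against the slide row as the whole cause, since within row 2 the difference between 2 and 1 mM was -0.94, against -0.89 over all arrays. The slots followed the doses in order from 1 to 8. A steady gradient along them would need -0.361 per slot, while within doses the slope was 0.0831 ± 0.117 (SE), which argues against a steady gradient as the whole cause. A position effect that is not steady along the slots stays open. A uniform loss of messenger RNA alone would move all ORFs alike. Over the 183 ORFs above background on all arrays the changes had an SD of 1.099 against a median SE of 0.260, so ORFs did not all move alike. This spread does not tell whether a loss common to all ORFs lies under the fall of the median, which stays open. A lower level of many transcripts in treated cells, breakdown that differs between transcripts and a difference in RNA quality were not tested and stay open. A difference in spike-in amount was not measured apart, but the Bd_r level per spike-in differed by 0.0773 ± 0.232 (SE).

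Under the main scaling, 10 ORFs rose at 2 mM although no 2 mM array showed them well above background. Under spike-in scaling 4 of the 10 had a positive change and 1 was called as a rise. That scaling moves all 10 by the same -1.08, so alone it does not show whether these rises come from the main scaling. Their median change was 1.04 under the main scaling and -0.05 under spike-in scaling. The 25 b-number probes tested had medians of 1.06 and -0.07. Without a filter on dim ORFs the median over 3205 ORFs was 1.41 under the main scaling. Rises of this size were thus common near background, and whether the 10 were more than that stays open.

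Neighbouring ORFs changed together at 2 mM. Across 223 pairs of adjacent tested ORFs on the same strand with gaps of at most 100 bases the correlation was 0.717, above the highest of 10000 shuffles, 0.245. Adjusted for the mean level over all arrays, the correlation was 0.746. That mean includes the treated arrays and so contains the change itself. The adjustment therefore cannot test whether neighbours shared a level in untreated cells, and a shared baseline level stays open. Across 76 adjacent pairs on opposite strands the unadjusted correlation was 0.191, lower by 0.526. This difference exceeded the highest of 10000 shuffles of the pair classes (0.402). This is consistent with shared transcription of same-strand neighbours, as a hypothesis, but 38 same-strand pairs with wider gaps also had a correlation of 0.583.

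Splits of the 6 arrays at 0 and 1 mM into other groups of 3 were compared with the real one. The real split, 1 of 10, gave 334 ORFs, and the highest of the others gave 0. It gave 7 runs by camera, while another split gave 8, and 3 of the 10 splits gave 7 or more. The 10 splits are too few for a share under 0.05 in either result.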
